A study of Mus musculus with 9 samples.

How the data were processed

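Gene expression was measured by RNA sequencing of mouse liver in 9 libraries, 5 from control mice and 4 from mice given antibiotics. Per the labels' protocols, livers were frozen in RNAlater, RNA was taken with Trizol and cleaned on RNeasy columns, and libraries were made with a stranded poly(A) kit. A stranded kit keeps the orientation of the transcript, but no source used here states whether the strand was used in the counting, so genes with exons on the opposite strand of another gene carry that uncertainty. The deposited table holds estimated counts per gene, which the authors made with Salmon against GRCm38, per the submitters' processing notes. The version of Salmon, its settings and the annotation release are not given in the sources used here. All values in the deposited table were whole numbers, so the estimated counts had been rounded before deposit and were used as they stood. All 54393 gene identifiers of the table, version included, occur in GENCODE release M21 (55450 genes, GRCm38), which supplied the symbols' positions, biotypes, exon lengths and GC content.

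Groups and replicate numbers came from the sample labels. Library totals ran from 15422891 to 59179622 counts. Genes were kept by the filterByExpr function of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 14873 genes. Counts were scaled by TMM factors and fitted in R 4.3.3 with the quasi-likelihood F test of edgeR, with group as the only term and Benjamini-Hochberg adjustment over the tested genes. A gene passed at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. Normalised read counts are CPM on TMM-scaled libraries, and their errors are SDs over the libraries of a group. The biological coefficient of variation was 16.7%. On simulated counts for the same 14873 genes, in 5 against 4 libraries, the test recovered 42% of the genes changed 1.5-fold, 82% at 2-fold, 96% at 3-fold and 100% at 4-fold. In that simulation 9 of 169 calls were false, and simulated libraries with no change gave 0 calls. Floors for counts of 0 cover counting error only.

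The test, its covariates, 37 gene lists, the cell type markers, the alternatives and the rule for naming genes were fixed before the data were examined. Under that rule the text could name the 12 largest rises and 12 largest falls among passing genes with a mean of at least 1 CPM and no overlap between the groups. It could also name the 5 genes with the smallest p, up to 4 members of each list with the smallest p, and a fixed set of liver genes. Genes outside the rule are named as chosen after their values were seen, and 1 gene that the rule names is not reported here. Each list with at least 5 tested members, 36 in all, was tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, Benjamini-Hochberg adjustment over the lists), with an estimated correlation and fry as alternatives. A list score is the mean over members of the log2 CPM (prior count 2) relative to the control mean. In simulated data a list of 20 genes shifted 1.4-fold was called, and 0 of 50 unshifted lists were. Those simulated genes were drawn independently of each other. The result therefore does not cover real lists whose members vary together, such as antigen presentation with an estimated correlation of 0.89.

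The alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter or a filter at 1 CPM, other thresholds, library sizes without the 10 most abundant genes, a replicate block, and omission of each library. Thinning of all libraries to the smallest total and a correction for GC content were added after seeing the data. To find genes that share reads with a close copy, the longest transcript of each named gene was searched against all M21 transcripts with BLAST+ 2.17.0 (at least 95% identity over 200 nt), and 17 of 113 genes had such a copy. Other splits of the 9 libraries into 5 and 4 were refitted for 100 splits. No pair of libraries agreed within sampling noise (the lowest chi-square per degree of freedom within a group was 20.3), so all 9 were kept as separate samples. The labels do not say that each library came from its own mouse, although the design text gives 4 to 5 per group, so p-values measure the spread between these libraries.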

Results

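Liver RNA was sequenced from mice on the purified diet AIN-76a whose gut bacteria had been depleted with antibiotics that are not absorbed from the gut, and from conventional control mice on the same diet. The comparison asks which liver transcripts differ with the microbiota. The 5 control libraries held 41047847, 49628737, 32495190, 41796911 and 28156248 estimated counts (replicates 1 to 5). The 4 antibiotics libraries, labelled replicates 1, 2, 3 and 5, held 15422891, 18001886, 18504624 and 59179622. Antibiotics library 5 was thus the deepest of all, and the other 3 were shallower than every control. The Y-linked gene Ddx3y had at least 745 counts in every library and Xist at most 5.

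Antibiotic treatment went with more transcript of Cyp7a1, the rate-limiting enzyme of bile acid synthesis, from 16.2 ± 7.67 CPM in controls (SD, n = 5) to 63.2 ± 27.7 CPM (SD, n = 4). The metallothioneins Mt1 and Mt2, which bind zinc and copper, rose 3.61-fold and 4.03-fold. Slc43a1, a transporter of large neutral amino acids, rose 2.95-fold (6.25 ± 1.36 to 18.5 ± 3.95 CPM). Transcripts of Bhlha15, a transcription factor of secretory cells, fell from 3.14 ± 1.22 to 0.443 ± 0.236 CPM, and those of the retinol dehydrogenase family member Dhrs9 from 4.26 ± 1.32 to 0.66 ± 0.459 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 398 of 14873 genes differed between the groups, 242 higher and 156 lower with antibiotics.

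**Figure D1:**
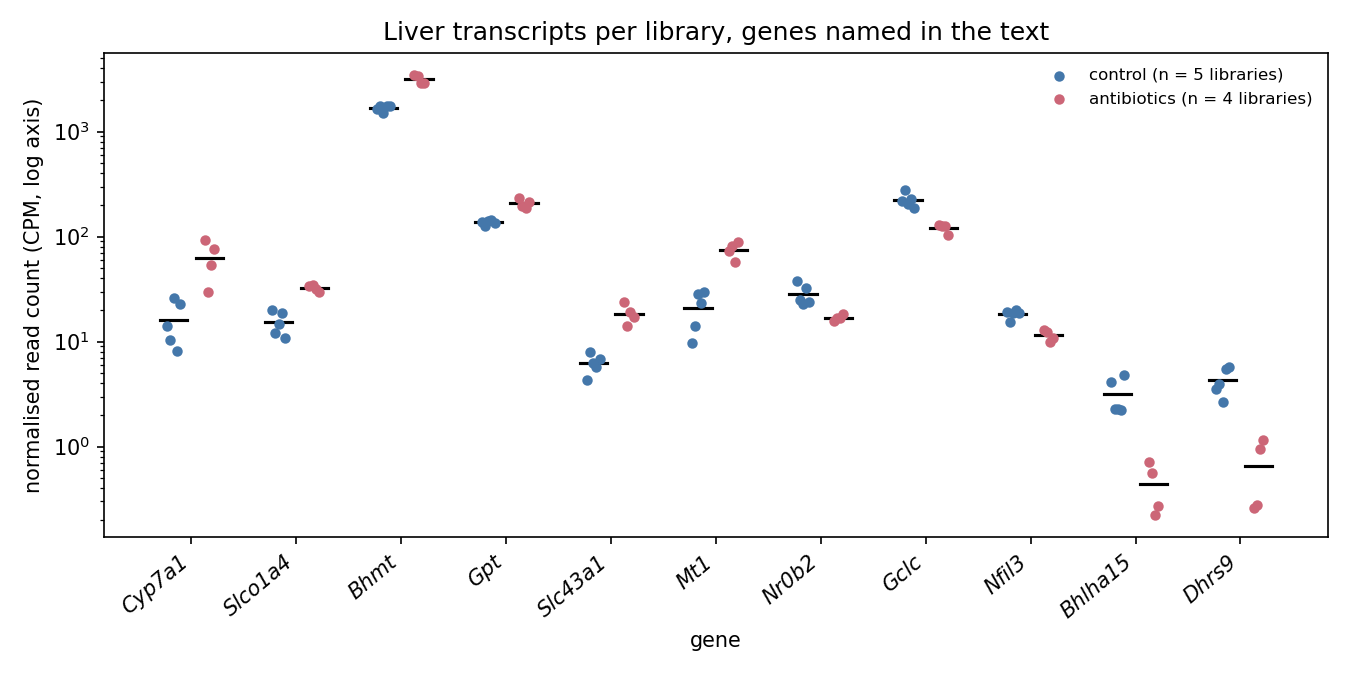
Normalised read count (CPM, log axis) of 11 genes named in the text in each library, for 5 control and 4 antibiotics libraries; points are libraries and black lines are group means. For each of the 11 genes all antibiotics libraries lie on one side of all control libraries, as for Cyp7a1, with means of 16.2 and 63.2 CPM. For Cyp7a1, Slc43a1, Mt1, Bhlha15 and Dhrs9, named among the largest rises and falls, this was a condition of the naming rule.

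Among the largest rises, Cyp7a1 (ENSMUSG00000028240.2, chromosome 4, 6265612 to 6275633, GRCm38) had a log2 fold change of 1.98 ± 0.37 (SE, adjusted p = 0.0239). Mt1 (chromosome 8, 94179082 to 94180327) changed by 1.85 ± 0.28 (adjusted p = 0.0140), and Slc43a1 (chromosome 2, 84838850 to 84863594) by 1.56 ± 0.18 (adjusted p = 0.00371). Gpcpd1, a glycerophosphocholine phosphodiesterase, rose 2.59-fold and Cxcl11, a chemokine gene annotated as a polymorphic pseudogene, 2.41-fold. Mterf2, Lrtm1, Atp6v0d2, Gm14097, Gm11266 and the pseudogene Gm35570, a near copy of Idi1, completed the 12 largest rises. Among the falls, Bhlha15 (chromosome 5, 144190286 to 144194441) changed by -2.94 ± 0.40 (adjusted p = 0.00832) and Dhrs9 (chromosome 2, 69380445 to 69404533) by -2.51 ± 0.39 (adjusted p = 0.0140). The other 10 were Rec8, Mup18, Mthfd2, Cyp1a1, Aldh18a1, Peg10, Nfxl1, Mup17, Lrp2 and Pkmyt1, with log2 fold changes from -1.35 to -1.10. Among the 5 genes with the smallest p-values were Hmgn2, a nucleosome-binding protein gene (log2 fold change 0.83 ± 0.08), Pcsk4 (1.12 ± 0.10), Gm4737 and Abhd15. Gm4737 shares 2083 nt at 99.7% identity with Ahcy, so counts could have been split between them, and Mup17 and Mup18 each have 15 close copies. Hmgn2 has a close copy in Gm10282. Exons of Abhd15, Gm14097, Mt2, Cxcl11 and Pkmyt1 overlap a gene on the opposite strand.

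The groups did not overlap in 380 of the 398 genes, and in 8.88% of all tested genes against 1.59% by chance. At least a 2-fold change was seen in 62 of the 398. The count was 36 without antibiotics library 5, 53 without library 1, 56 without library 3 and 216 without library 2, and 171, 165 and 144 without control libraries 1, 2 and 4. Of the 398 genes, 28 passed in all 9 fits that left out 1 library, among them Bhlha15, Dhrs9, Slc43a1, Bhmt, Ahcy, Gpt, Dbp, Gclc and Slco1a4, while Lrp2 passed in 0. Cyp7a1 passed in 4 of these fits, with adjusted p of 0.0546 and 0.0518 without control libraries 1 and 2, and of 0.0766, 0.0603 and 0.0806 without antibiotics libraries 1, 3 and 5. Mt2 had adjusted p of 0.0574, 0.0509 and 0.0623 without antibiotics libraries 1, 3 and 5, and Mt1 of 0.0533 without library 5. Asl, Nfxl1 and Gm11266 passed in 8 of the 9 fits, Oat, Esrra, Rec8, Gm14097 and Gm35570 in 7, and Gpcpd1, Fmo2, Sult1a1, Lipe and Mthfd2 in 6. Cyp1a1 and Cyp3a13 passed in 5, Lrtm1 and Aldh18a1 in 4, Mterf2 and Peg10 in 3, Cxcl11, Atp6v0d2 and Mup18 in 2 and Mup17 and Pkmyt1 in 1. DESeq2 called 975 genes.

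Of 36 gene lists, camera called 12. No call held with an estimated correlation, and 63 of 100 splits of the libraries, the real one included, gave at least as many called lists, so the lists are described mainly by their members. With fry 4 calls held. These were the amino acid list (adjusted p = 0.00537), the unfolded protein response (0.0315), female-biased genes (0.00565) and adipose markers (0.00316). Exact permutation of the list scores over the 126 splits of the libraries gave 10 of 36 lists an unadjusted p under 0.05 and 0 after adjustment (two-sided, lowest adjusted p = 0.0571), where the smallest unadjusted p the design allows is 0.00794.

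Genes of amino acid, urea cycle and one-carbon metabolism were mostly higher with antibiotics: 10 of 29 tested members rose, 0 fell, and 20 had an unadjusted p under 0.05. Adjusted over the list alone, 18 were higher and 1 lower. Bhmt, which remethylates homocysteine with betaine, rose from 1684 ± 111 to 3155 ± 300 CPM (log2 fold change 0.91 ± 0.10, adjusted p = 0.00326). Ahcy, which splits S-adenosylhomocysteine, rose 1.54-fold, Cth, the cystathionine lyase, 1.60-fold, and the alanine aminotransferase Gpt 1.51-fold. The median log2 fold change of the list was 0.34 (camera adjusted p = 1.98e-13, and adjusted p = 0.112 with an estimated correlation). Bhmt and Ahcy each have 2 close copies, and Cth did not pass without antibiotics library 3 (adjusted p = 0.0501). The list score was 0.28, 0.35, 0.31 and 0.10 in antibiotics libraries 1, 2, 3 and 5, where the score of mitochondrially encoded mRNAs, a sign of RNA quality, was 0.35, 0.58, 0.41 and -0.06. Among controls both scores were highest in library 3, at 0.09 and 0.27.

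Among 16 genes of bile acid synthesis and conjugation, Cyp7a1 was the 1 gene to pass with edgeR (adjusted over the list alone, also 1), where DESeq2 called 2 higher and voom 1. That list had a camera adjusted p of 0.212 and an exact permutation p of 0.00794 (adjusted p = 0.0571). Cyp8b1, the 12-alpha-hydroxylase, measured 286 ± 18.1 and 318 ± 61.7 CPM (adjusted p = 0.513). Nr0b2, the repressor SHP, fell from 28.4 ± 6.53 to 17.0 ± 1.02 CPM (adjusted p = 0.0322, and 0.0625, 0.0915, 0.0673, 0.0827 and 0.0789 without control library 4 and antibiotics libraries 1, 2, 3 and 5), and the orphan receptor Esrra rose 1.51-fold. These were the 2 that passed of 20 nuclear receptors and partners (3 adjusted over the list alone, camera adjusted p = 0.125). Nr1h4, which encodes FXR, had an adjusted p of 0.159. Of 15 tested bile acid and sterol transporters 1 passed, also adjusted over the list alone (camera adjusted p = 0.730): Slco1a4 rose 2.10-fold, while Abcb11 and Slc10a1 had adjusted p of 0.169 and 0.695. No gene of cholesterol synthesis and uptake passed with edgeR (0 of 25, 0 adjusted over the list alone, 4 at an unadjusted p under 0.05, 0 with DESeq2 or voom, camera adjusted p = 0.936). The list's median was -0.01 and its mean -0.03, while camera placed it higher than other genes. In fatty acid and triglyceride synthesis 0 of 23 passed with edgeR, 1 adjusted over the list alone, 5 unadjusted, 1 with DESeq2 and 0 with voom (camera adjusted p = 0.0666). That list was called lower without control library 3 (adjusted p = 0.00669), control library 5 (0.00982) or antibiotics library 2 (0.00024), and had an adjusted p of 0.767 over all libraries with an estimated correlation. Camera also called it lower with no filter on low counts (adjusted p = 0.00732) and with the replicate block (0.0304). In fatty acid oxidation and ketogenesis 0 of 29 passed with edgeR, 6 adjusted over the list alone, 9 unadjusted, 7 with DESeq2 and 0 with voom (camera adjusted p = 0.0668). That list was called higher without control library 5 (adjusted p = 0.00317) or antibiotics library 3 (0.00811), and also had 0.767 with an estimated correlation. Camera also called it higher after GC correction (adjusted p = 0.0393). Srebf1 in the synthesis list and Cpt1a in the oxidation list were nearest to passing, with adjusted p of 0.0599 and 0.0585. Both were higher with antibiotics, Srebf1 against the median of its list. In glucose metabolism 1 of 20 passed, also adjusted over the list alone (camera adjusted p = 0.590): Igfbp1 fell from 76.0 ± 32.5 to 28.0 ± 9.66 CPM and passed in 3 of the 9 fits that left out 1 library, and Pck1 had an adjusted p of 0.809.

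Genes of phase I xenobiotic metabolism went both ways: 4 of 38 rose and 4 fell (9 and 5 adjusted over the list alone). Fmo2, a flavin monooxygenase, rose 2.23-fold (9.25 ± 2.67 to 20.6 ± 4.31 CPM, adjusted p = 0.0188) and Cyp3a13 1.36-fold, and the aryl hydrocarbon receptor target Cyp1a1 fell from 1.51 ± 0.198 to 0.632 ± 0.202 CPM. The list median was 0.14 (camera adjusted p = 0.0261, and adjusted p = 0.584 with an estimated correlation). The call ended without control library 3 (adjusted p = 0.115), control library 4 (0.0731) or antibiotics library 1 (0.103), with a filter at a mean of 1 CPM (0.0892), with a block on replicate numbers (0.0558) and after thinning to the shallowest library (0.0561). Cyp3a11 and Cyp2b10, targets of PXR and CAR, had adjusted p of 0.271 and 0.551. In phase II metabolism 2 of 41 rose and 2 fell (6 and 11 adjusted over the list alone, camera adjusted p = 0.305). The sulfotransferases Sult1b1 and Sult1a1 rose 1.75-fold and 1.63-fold. Gclc, the catalytic subunit of glutathione synthesis, fell from 223 ± 34.1 to 121 ± 12.1 CPM (log2 fold change -0.89 ± 0.12, adjusted p = 0.00767), as did Ugt2b5 (-0.44 ± 0.10, adjusted p = 0.0442), a transcript with a close copy in Ugt2b38. Gclc passed in all 9 fits that left out 1 library, and Ugt2b5 only in that without control library 3 (adjusted p = 0.0428, otherwise 0.0521 to 0.122). Gclc was also the 1 gene to pass of 17 in the oxidative stress list, where 8 were lower adjusted over the list alone, among them Gstm1, Txnrd1 and Gsta1. The median was -0.35 (camera adjusted p = 1.68e-05, and adjusted p = 0.296 with an estimated correlation). Gsta1 has 3 close copies and Gstm1 has 1, and Gsta1 reached at most 2.43 CPM in the antibiotics libraries.

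In the unfolded protein response list 0 of 19 genes passed with edgeR, 7 were lower adjusted over the list alone, 9 had an unadjusted p under 0.05, 6 passed with DESeq2 and 0 with voom. Dnajb9, Manf, Hyou1 and Atf4 had log2 fold changes from -0.56 to -0.31, and the list median was -0.23 (camera adjusted p = 4.94e-05, and adjusted p = 0.278 with an estimated correlation). Of the immediate early genes 0 of 15 passed with edgeR, 1 adjusted over the list alone, 5 at an unadjusted p under 0.05 and 1 each with DESeq2 and voom. Dusp1 measured 27.5 ± 6.05 and 14.5 ± 4.95 CPM (adjusted p = 0.0508). That list had a median of -0.28 (camera adjusted p = 0.00330, and adjusted p = 0.296 with an estimated correlation). Mt1 and Mt2 were the 2 passing members both of 28 acute phase genes (2 adjusted over the list alone, camera adjusted p = 0.330) and of 15 glucocorticoid- and stress-induced genes (4 adjusted over the list alone, camera adjusted p = 0.125, and 0.0244 without control library 1, and 0.618 over all libraries with an estimated correlation). In both lists the median was below 0, at -0.07 and -0.11, and the mean and the test above it. The acute phase genes Saa1 and Saa2 varied widely between libraries of 1 group, at 590 ± 741 and 524 ± 675 CPM in controls. No cell cycle gene passed with edgeR (0 of 17, 0 adjusted over the list alone, 2 unadjusted, 0 with DESeq2 or voom, camera adjusted p = 0.125). With no filter on low counts camera called the cell cycle list lower (adjusted p = 0.0368).

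Clock genes differed between the groups, 7 of 21 higher and 1 lower (11 and 6 adjusted over the list alone). Dbp, a clock output transcription factor, rose from 63.6 ± 7.50 to 112 ± 14.3 CPM (log2 fold change 0.82 ± 0.11, adjusted p = 0.00767). The deubiquitinase Usp2 and the kinase Wee1 rose 2.19-fold and 2.30-fold, and Nfil3, which represses Dbp targets, fell from 18.3 ± 1.82 to 11.5 ± 1.41 CPM (adjusted p = 0.0140). Per3 rose 2.27-fold, and the core activators Arntl and Npas2 had log2 fold changes of -1.09 ± 0.27 and -1.29 ± 0.36 (adjusted p = 0.0597 and 0.0776). Per3, Arntl and Npas2 were chosen after their values were seen. The list median was 0.33 (camera adjusted p = 0.00149, and adjusted p = 0.377 with an estimated correlation). Per3 passed in 3 of the 9 fits that left out 1 library, Wee1 in 5, Usp2 in 6 and Nfil3 in 7. No label gives the time at which livers were taken.

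**Figure D2:**
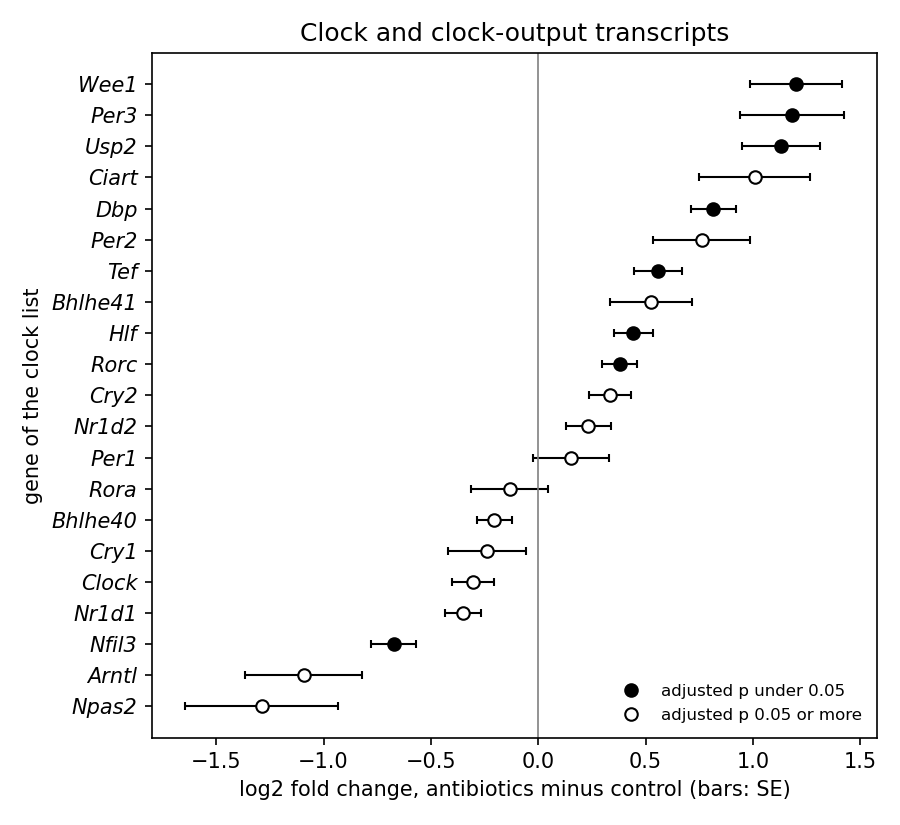
Log2 fold change (antibiotics minus control, x axis, bars are SE) of the 21 genes of the clock list (y axis), from 5 control and 4 antibiotics libraries; filled points passed at an adjusted p under 0.05. The 8 passing genes run from Wee1 at 1.20 to Nfil3 at -0.67.

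Of 9 tested genes that are higher in female liver, 4 rose and 0 fell, among them Fmo2, Atp6v0d2 and the acyl-CoA thioesterase Acot3 (6 higher adjusted over the list alone, camera adjusted p = 4.48e-08, and adjusted p = 0.10 with an estimated correlation). The other members of that list of 20 were not tested, with at most 29 counts in any library of either group. Acot3, which overlaps its close copy Gm49366, measured 16.1 ± 16.7 CPM with antibiotics and passed in 2 of the 9 fits that left out 1 library. Of 19 male-biased genes 1 fell, also adjusted over the list alone (camera adjusted p = 0.135, and 0.0305, 0.0438 and 0.0195 without control library 4 and antibiotics libraries 1 and 3, and 0.793 over all libraries with an estimated correlation): Elovl3, a fatty acid elongase, went from 313 ± 56.3 to 190 ± 37.7 CPM, while Mup7 had an adjusted p of 0.384. Camera also called the male-biased list lower with the replicate block (adjusted p = 0.00661) and with no filter on low counts (0.0398). Among 17 pericentral genes Oat and Rnf43 rose 1.63-fold and 1.57-fold and Cyp2c29 fell from 1055 ± 258 to 546 ± 168 CPM (4 higher and 1 lower adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.0133, and 0.0731 without control library 4, and adjusted p = 0.422 with an estimated correlation). Among 18 periportal genes, 11 of which had an unadjusted p under 0.05, Asl and Sds rose and Cdh1 fell (8 higher and 1 lower adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00306, and adjusted p = 0.422 with an estimated correlation). Of the 9 fits that left out 1 library, Sds passed only in that without control library 4 (adjusted p = 0.0160, otherwise 0.0574 to 0.109) and Cdh1 only in that without control library 2 (adjusted p = 0.0415, otherwise 0.0504 to 0.111). Elovl3 passed in 3 of these fits, and Rnf43 and Cyp2c29 in 2 each.

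The histone acetylation list, 38 enzymes and readers, had 1 passing member (3 adjusted over the list alone, camera adjusted p = 0.739). Brd2, a bromodomain reader of acetylated histones, fell from 82.4 ± 2.11 to 66.8 ± 4.97 CPM (log2 fold change -0.30 ± 0.07, adjusted p = 0.0384), and passed only without control library 3 (adjusted p = 0.0426) or 5 (0.0437) among the 9 fits that left out 1 library. Brd2 overlaps H2-DMa on the opposite strand. The deacetylase Hdac3 measured 31.0 ± 0.544 and 32.6 ± 2.10 CPM (adjusted p = 0.597), and the acetyl-CoA enzymes Acly and Acss2 had adjusted p of 0.50 and 0.922. Among genes for short-chain fatty acid sensing, transport and use, 0 of 15 passed with edgeR, 2 adjusted over the list alone (Slc16a7 and Acsm3, both higher), 5 at an unadjusted p under 0.05, 2 with DESeq2 and 0 with voom (camera adjusted p = 0.0666). That list was called higher without control library 1 (adjusted p = 0.0224), control library 2 (0.0197) or antibiotics library 5 (0.0123), and had 0.608 over all libraries with an estimated correlation. Camera also called it higher with a filter at a mean of 1 CPM (adjusted p = 0.0464), after thinning (0.0393) and after GC correction (0.0393). The receptor gene Ffar2 had 0 to 3 counts per library and Ffar3 had 0 in every library, so neither was measurable at this depth.

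Markers of macrophages, T and NK cells and antigen presentation stood apart in control library 2, while its neutrophil and monocyte score (0.22) lay below that of control library 3 (0.56). Macrophage markers had a median log2 fold change of -0.39, with 0 of 16 passing in edgeR, 1 at an unadjusted p under 0.05 and 0 with DESeq2 or voom (camera adjusted p = 0.00562, and adjusted p = 0.767 with an estimated correlation). That call ended without control library 2 (adjusted p = 0.318), where H2-Aa, an MHC class II gene, stood at 140 CPM against 14.8 to 24.4 CPM in the other controls. Without that library the interferon-induced genes had a median of 0.12 and were called higher (adjusted p = 0.00137, and adjusted p = 0.563 with an estimated correlation), against -0.14 with all libraries (camera adjusted p = 0.861). Of the interferon-induced genes 1 passed with edgeR without control library 2. With all libraries none did (0 of 43, 4 unadjusted, 1 with DESeq2, 0 with voom), nor any of 21 antigen presentation genes (1 unadjusted, 0 with DESeq2 or voom, camera adjusted p = 0.125) or of 28 microbial sensing genes (4 unadjusted, 1 with DESeq2, 0 with voom, camera adjusted p = 0.266). The antigen presentation list was called lower without control libraries 1, 3 or 4 (adjusted p = 0.0348, 0.0394 and 0.0289), and had 0.817 over all libraries with an estimated correlation. Camera also called it lower with no filter on low counts (adjusted p = 0.0398) and with the replicate block (0.0241). Without control library 2 its direction turned to higher, uncalled (median 0.09, camera adjusted p = 0.0580). For the macrophage, interferon, antigen presentation and microbial sensing lists, 0 genes passed adjusted over the list alone.

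**Figure D3:**
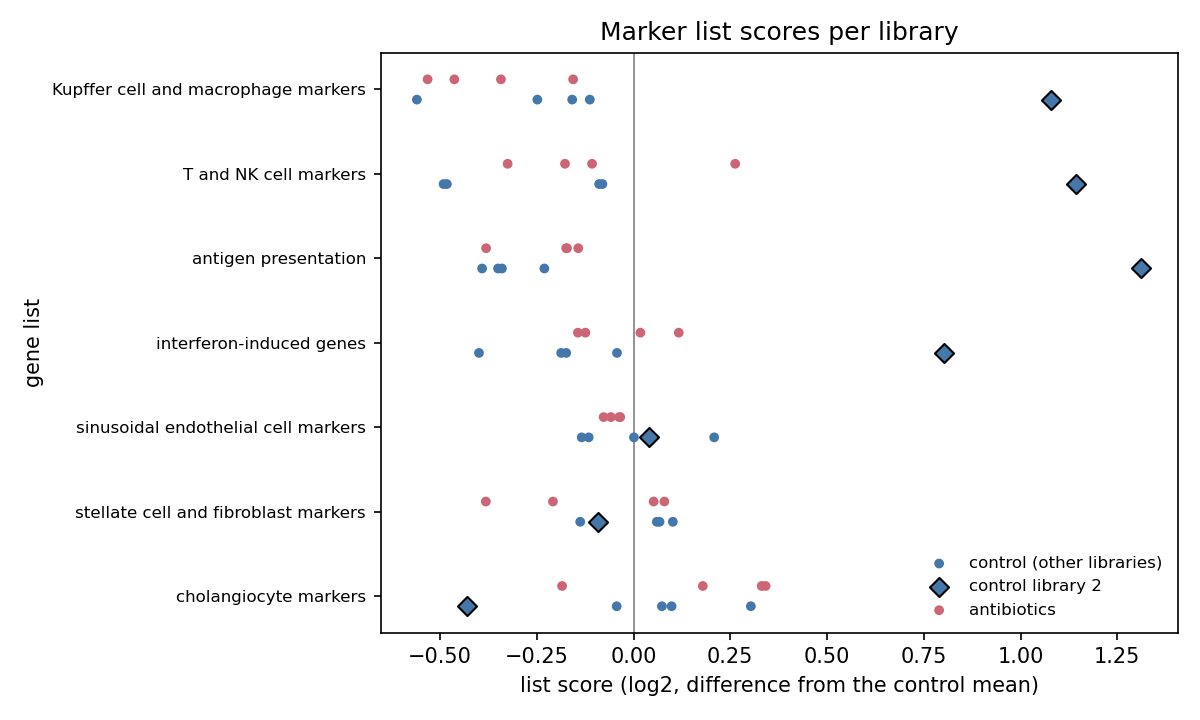
Score of 7 gene lists (y axis) in each library as the mean log2 difference from the control mean (x axis); points are libraries, and the diamond is control library 2. Control library 2 stands at 1.08 for macrophage markers, while its sinusoidal endothelial score is 0.04.

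The remaining marker lists gave 0 passing genes with edgeR, DESeq2 and voom for T and NK cells (9 tested, 0 unadjusted, camera adjusted p = 0.590), B and plasma cells (10 tested, 1 unadjusted, 0.266), neutrophils and monocytes (5 tested, 1 unadjusted, 0.590), sinusoidal endothelium (14 tested, 1 unadjusted, 0.339), stellate cells (16 tested, 0 unadjusted, 0.434) and erythroid cells (5 tested, 1 unadjusted, 0.0509). The erythroid list was called higher without control libraries 1, 2 or 5 (adjusted p = 0.0224, 0.0433 and 0.00467) or antibiotics libraries 1 or 5 (both 0.0117), and had 0.608 over all libraries with an estimated correlation. Camera also called it higher with a filter at a mean of 1 CPM (adjusted p = 0.0481), after thinning (0.0324) and after GC correction (0.0363). Adjusted over the list alone, the count was 1 for the erythroid list and 0 for the other 5. Only 2 of 14 pancreatic acinar genes were tested, neither passed with any of the 3 tools, at an unadjusted p under 0.05 or adjusted over the list alone, and that list had no camera test. Krt23 rose among 9 cholangiocyte markers (also 1 adjusted over the list alone, camera adjusted p = 0.345) but passed in 0 of the 9 fits that left out 1 library. Among 6 adipose markers Lipe, the hormone-sensitive lipase, rose 1.68-fold (2 adjusted over the list alone), and the list median was 0.75 (camera adjusted p = 0.00271, and adjusted p = 0.112 with an estimated correlation). Adipoq, Plin1, Lep and Retn of that list were not tested, with at most 17 counts in any library. All mitochondrially encoded transcripts, ribosomal RNA included, made up 5.42 ± 0.864% of counts in controls and 6.58 ± 0.961% with antibiotics. The 13 mitochondrially encoded mRNAs alone, a sign of RNA quality, had a median log2 fold change of 0.32 (camera adjusted p = 0.00205, and adjusted p = 0.587 with an estimated correlation). Of these mRNAs 0 passed with edgeR, DESeq2 or voom, 0 adjusted over the list alone and 4 at an unadjusted p under 0.05.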

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

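The tests of depth, GC content, clock phase and the immune signal of control library 2 were chosen after the results they bear on were seen. The splits of the libraries were not. The test within groups on the clock was recorded as set beforehand. Its clock index, however, uses the 15 genes of the phase test, a test chosen after their values were seen. It was scored on the called genes, so its p-value is not that of a fully planned test.

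The 398 genes were set against other splits of the 9 libraries, depth and GC content. Of 100 splits, 1 (the real one) gave as many genes, and the highest other gave 39. Chance assignment is thus an unlikely source of the count but is not excluded, as 100 of the 126 possible splits were refitted. The splits cannot tell the treatment from another difference that runs with the groups. Lower depth of 3 antibiotics libraries is argued against as the whole source: with all libraries thinned to 15422891 counts, 70.6% of the 398 calls remained with their direction. After correction for GC content 96.0% of the 398 calls remained with their direction. The 12 called lists stand differently, since 63 of 100 splits gave as many and the highest other gave 21, so chance assignment could give their number. Effects of the antibiotics and of the lost bacteria stay open and untested.

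The clock genes may reflect livers taken at a later phase of the day in treated mice, a technical explanation that the labels cannot settle. Of 10 genes that peak around dusk and 5 that peak around dawn, all 15 moved in the direction of a later daytime phase. Called genes outside the clock list also followed the clock index within groups, with the difference between the group means removed: 71.5% of 390 had the sign of their group difference (exact permutation within groups, one-sided p = 0.0222), and omission of single libraries gave 65.1% to 73.3%. Clock phase could therefore carry part of the other differences. A shift of the rhythm by the treatment makes the same predictions and stays open.

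Immune transcripts stood high in control library 2, such as Cd74 at 297 CPM against 33.7 to 58.3 CPM in the other controls. The scores of macrophage, T and NK cell and antigen presentation lists there, which have 0 genes in common, were 1.08, 1.14 and 1.31, each above those of all 8 other libraries. In the mean of the other controls, 16 of 16 macrophage and 20 of 21 antigen presentation genes exceeded 1 CPM. Only 1 of 9 T and NK markers did, so that score rests on genes with few counts. Whether that piece of liver held more immune cells was not tested. A lower share of hepatocytes is argued against, since the highest of the endothelial, stellate and cholangiocyte scores was 0.0404. Depth is argued against too, since the macrophage score exceeded that of the deeper antibiotics library 5 by 1.24. No biological explanation was tested, as the design gives none for a single control.

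Within groups, 27 of 300 sets of values had a library far from the others, where chance gives about 1 in 20, or 15. In control library 2, H2-Aa (140 CPM), H2-Ab1 (109 CPM) and Ugt2b5 (1051 CPM) were high and Nfil3 (15.2 CPM) was low. Control library 4 was high for Sds (273 CPM) and low in the bile acid synthesis score (-0.16). Control library 5 was low in the bile acid and sterol transport score (-0.25) and high in the fatty acid oxidation score (0.22). Antibiotics library 5, with 59179622 counts, was low for Abcb11 (470 CPM), Gclc (103 CPM) and Cars (22.8 CPM) and high for Nr1i3 (184 CPM), Gsta1 (2.43 CPM) and Fgf21 (3.01 CPM). Antibiotics library 1 was low for Cxcl11 (2.68 CPM), in the B and plasma cell score (-0.81) and in the oxidative stress score (-0.49), and high for Rec8 (1.90 CPM). Antibiotics library 2 was low for Fmo2 (14.2 CPM) and high for Fasn (1621 CPM) and in the glucose metabolism score (0.0554). Antibiotics library 3 was high for Bckdhb (57.9 CPM) and low in the antigen presentation score (-0.38).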

How the results depend on the processing

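The GC correction and the thinning were chosen after seeing the data. The count of 398 genes (242 higher, 156 lower) became 937 (527 and 410) at an adjusted p under 0.10, 62 (39 and 23) with at least a 2-fold change, 975 (516 and 459) with DESeq2 and 599 (340 and 259) after GC correction. The first 2 follow from the threshold; for the others the cause was not tested. Fits without 1 library gave 36 to 455 genes (28 to 276 higher, 8 to 191 lower). The count was 401 with RLE factors, 395 with upper-quartile factors, 413 with limma-voom, 373 with no filter, 404 with a filter at 1 CPM, 390 without the 10 most abundant genes and 315 after thinning to 15422891 counts, where 281 of the 398 calls remained. Same-numbered libraries did not deviate together in every pair (r = 0.086, -0.045, 0.164 and 0.246 for numbers 1, 2, 3 and 5). Whether the numbers pair the samples stays open, since the labels do not say and these correlations cannot exclude it. A replicate block over those 8 libraries gave 179 genes (120 and 59), against 144 (97 and 47) for the same libraries without it. Antibiotics libraries 1, 3 and 5 correlated best with the control of their own number, and library 2 with control library 4 (r = 0.223).

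Of 12 called lists, 0 held with an estimated correlation and 4 with fry; the other settings gave 12 to 16. The phase I list lost its call with the 1 CPM filter (adjusted p = 0.0892), the replicate block (0.0558) and thinning (0.0561), and the pericentral list with the replicate block (0.0799). The interferon list reversed without control library 2, from a median of -0.14 to 0.12 (the range over fits without 1 library was -0.23 to 0.12). The cause was not tested beyond the immune signal of that library. Over all settings the named genes were called or uncalled as before in 2081 cases, lost the call in 336, gained it in 61 and reversed in 0. For lists the numbers were 571, 31, 36 and 1. A reversal was counted only where a result was called in at least 1 of the fits compared. Depth limits transcripts with few counts most in the 3 antibiotics libraries with 15422891 to 18504624 counts.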

Other observations

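The groups described here, and the tests on them, were chosen after the values were seen. Genes for charging tRNAs in the cytosol fell among the called genes: Cars fell from 40.6 ± 6.42 to 25.4 ± 1.76 CPM (edgeR adjusted p = 0.0156) and Yars from 36.0 ± 3.55 to 26.7 ± 2.01 CPM (adjusted p = 0.0330), and 5 of 20 cytosolic aminoacyl-tRNA synthetases passed. Of 17 mitochondrial synthetases 0 passed with edgeR, with a median log2 fold change of 0.02. In a mixed list of 22 known ATF4 targets, of amino acid synthesis and uptake and of stress responses, 5 fell: Mthfd2, Aldh18a1, Psph, Slc1a4 and the stress gene Sesn2. In the opposite direction, 4 of 22 genes of branched-chain amino acid degradation rose, among them Ivd (120 ± 5.81 to 161 ± 19.9 CPM) and Bckdhb. Of the 9 fits that left out 1 library, Cars, Mthfd2 and Sesn2 passed in 6, Yars, Aldh18a1 and Ivd in 4, Psph in 3, and Slc1a4 and Bckdhb in 2 each (for Bckdhb, without control library 3 or 5).

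One hypothesis is that each of these groups may have moved as a whole. It was tested on the members that had not been called. Their median log2 fold change was -0.19 for 15 synthetases (14 negative), -0.45 for 17 genes of the ATF4 group (13 negative) and 0.15 for 18 genes of branched-chain degradation (17 positive), all in the direction of the called members. For the whole groups, exact permutation of the libraries gave unadjusted p of 0.00794, 0.0159 and 0.00794, and adjusted p of 0.0198, 0.0265 and 0.0198 over only the 5 groups chosen after the values were seen; over the 36 planned lists the same 0.00794 gave 0.0571. With camera, the adjusted p over the same 5 groups with an estimated correlation was 0.107, 0.0281 and 0.112, so only the ATF4 group passed that stricter test. Since the groups were chosen on these libraries, and members of the ATF4 group had been seen in other lists, these values do not give independent evidence of the direction.

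Major urinary proteins were lower for 4 of 21 tested genes, among them Mup15 (2281 ± 507 to 1069 ± 328 CPM, edgeR adjusted p = 0.0337, passing in 3 of the 9 fits that left out 1 library). Mup15 shares at least 95% identity with 15 other genes, and the adjusted p for the family was 0.193 with an estimated correlation. The pseudogene Gm20656 (chromosome 3, 64447967 to 64460095) had 12 to 33 counts in every control library and 0 in every antibiotics library. Against a floor of 3 counts over the antibiotics group it was at least 22.4-fold lower with antibiotics, and 2 other genes share near-identical sequence with it. A second pseudogene, Gm13080 on chromosome 4, had 6 to 22 counts in every control library and 0 in every antibiotics library. Against the same floor Gm13080 was at least 12.7-fold lower, and it was not searched for close copies. The cause of these absences was not tested.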
